A study of Mus musculus with 4 samples.

How the data were processed

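RNA and T cell receptors (TCRs) were measured in sorted CD3+ cells from the brains of mice with Glioma-005 tumors, with 1 RNA library and 1 TCR library for IgG and the same for anti-CTLA-4, each made from a pool of 3 tumors. The deposited RNA matrices hold UMI counts for 32285 genes in barcodes already called as cells, and Cell Ranger 3.1 with mm10 is what the submitters' processing notes give. The deposited clonotype lists give for each clonotype a count of cells, that count as a fraction of the library, and the junction sequences of its TRA and TRB chains. How cells and clonotypes were called is not given in the sources used here. The clonotype lists hold no barcodes, so receptors were not joined to RNA.

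Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. This left out 1204 IgG and 424 anti-CTLA-4 barcodes with too few genes, and 494 and 176 above the mitochondrial limit, with some barcodes in both groups. Kept cells had a median of 2013 UMIs in the IgG library and 2807 in the anti-CTLA-4 library. Scrublet, as built into scanpy 1.11.5, was run per library at an expected doublet rate of 7% and marked 0 barcodes in either library, so doublet removal did not work. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering (leidenalg 0.10.2) of both libraries together at resolution 1.0, without correction between libraries. Clusters were named from marker genes fixed beforehand, but the numeric rule was set after seeing the data. It took the class of highest mean log2 marker ratio, above 0.6 and at least 0.25 above the next, with at least 3 markers each detected in 5% of cells. CD4 classes also needed Cd4 in 1.5 times as many cells as Cd8a, and the CD8 class Cd8a in 3 times as many as Cd4. A name was dropped where the 10 leading genes of a cluster held more markers of another class. Clusters are called cells of a type on this evidence alone. Clusters with a median under 1200 UMIs were treated as low in UMIs, a rule also set after seeing the data.

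UMIs were summed over the cells of a class in each library and divided by the class total to give CPM. Intervals at 95% were exact for counts (Poisson), ratios (conditional binomial) and shares (Clopper-Pearson), and Newcombe intervals were used for differences of shares. For a share of 0 the upper limit is 3 counts of the total. No test between treatments was made, since each had 1 library. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3. The rule for named genes, the gene lists, the comparisons and most other settings tried were fixed before the data were examined. Genes with at least 100 UMIs over both libraries, at least 50 CPM and detection in at least 5% of cells in the higher library, and a ratio of at least 1.5 were ranked. Receptor and immunoglobulin segments, mitochondrial, ribosomal, haemoglobin and sex-linked genes, unnamed gene models and markers of other cell types were left out of the ranking. The 10 highest and 10 lowest ratios were named in conventional CD4 and CD8 T cell-like cells and 6 each way in regulatory T cell-like cells, beside a panel of 43 genes. List examples were the 2 members of highest and the 2 of lowest ratio with at least 100 UMIs. Genes named for other cell types, cluster descriptions, Trbv19 and the glucocorticoid-type set were picked after their values were seen.

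For each of 24 gene lists the median and mean log2 ratio were taken over members with at least 20 UMIs. The median was placed among 10000 random lists of the same size, each member drawn from the 50 genes nearest in expression, and the percentile is a description only. List intervals came from Poisson draws of the counts. Shares of cells with a UMI of a gene were taken after thinning each cell to 1000 UMIs. Clonotypes of at least 2 cells were called expanded, and the larger TCR library was drawn down to the smaller 1000 times. No library of another sample was used.

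The other settings changed the clustering resolution, the number of variable genes, the centring of values per library, the cell filter, doublet removal, the scaling (TMM, median-of-ratios, mean over cells), the UMI minimum, the definition of classes (UMIs of Cd4, Cd8a, Cd8b1 and Foxp3 per cell) and the clonotype definition. Classes from UMIs per cell were drawn from all T cell clusters, the unnamed, low-UMI, proliferating and NK-like ones included. They therefore hold another set of cells than the cluster classes. Leaving out low-UMI clusters, the highest Scrublet scores, or cells with a C1qa, C1qb, C1qc, Apoe or Lyz2 UMI was added after seeing the data. On simulated data made from the class totals, 97% of genes set 2-fold apart in conventional CD4 and regulatory T cell-like cells and 98% in CD8 T cell-like cells came out at least 1.5-fold apart in the right direction. Among genes set equal, 0.893%, 0.862% and 0.905% came out at least 1.5-fold apart. Intervals held the true ratio in 95.3%, 95.8% and 95.4% of cases. The simulated counts were Poisson draws, which the intervals also assume, so this coverage was built in. Spread between cells was not simulated, so the coverage says nothing about it.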

Results

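T cells were taken from mouse brains bearing Glioma-005, a glioblastoma line implanted into the hippocampus of C57BL/6J mice aged 8 to 12 weeks. From day 7 the mice received either an antibody against CTLA-4, an inhibitory receptor that conventional T cells gain on activation and regulatory T cells carry at rest, or an isotype IgG. Brains were taken on day 35, immune cells were enriched on Percoll, and CD3+ cells were sorted for 5′ droplet sequencing of RNA and of T cell receptors (TCRs). Each treatment had 1 RNA library and 1 TCR library, and each library was made from a pool of 3 tumors. The IgG RNA library held 9746 barcodes and 21958921 UMIs, with a median of 1753 UMIs and 888 genes per barcode. The anti-CTLA-4 RNA library held 8139 barcodes and 27110165 UMIs, with a median of 2685 UMIs and 1134 genes. After the cell filter 8202 IgG and 7605 anti-CTLA-4 cells were left, of which 7032 and 5789 fell in T cell clusters. With 1 library per treatment no difference has a replicate check, and the intervals given are 95% intervals that cover counting error only. A log2 ratio is the CPM in the anti-CTLA-4 library over the CPM in the IgG library, from UMIs summed over the cells of a class.

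The sorted cells were mostly T cells in both libraries, and conventional CD4 T cell-like, regulatory T cell-like and CD8 T cell-like clusters were all present in number. Conventional CD4 T cell-like cells, the helper lineage, made up, of the T cell cluster cells, 21.8% (20.8 to 22.9) in the anti-CTLA-4 library and 16.9% (16.1 to 17.8) in the IgG library. Regulatory T cell-like cells, the suppressive lineage marked by Foxp3, made up 21.5% (20.4 to 22.6) in the anti-CTLA-4 library and 19.9% (18.9 to 20.8) in the IgG library. CD8 T cell-like cells, the cytotoxic lineage, made up 19.8% (18.8 to 20.9) in the anti-CTLA-4 library and 19.99% (19.1 to 20.9) in the IgG library. NK-like cells with the receptor genes Klrb1c and Ncr1 were 3.75% against 1.44% of the T cell clusters, and proliferating cells were 3.32% against 5.18%, anti-CTLA-4 against IgG. NK-like cells numbered 213 against 92 at a coarser and 221 against 108 at a finer clustering. One proliferating cluster, rich in mitochondrial RNA, held 0.622% against 2.25% of T cells, and the other held 2.69% against 2.93%. Among CD4 lineage cells the regulatory share was 49.6% (47.6 to 51.6) in the anti-CTLA-4 library and 54.0% (52.0 to 55.9) in the IgG library.

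The conventional CD4, regulatory and CD8 T cell-like shares gave no stable order between the libraries. The regulatory share of CD4 lineage cells was 45.5% against 45.6% without the clusters of low UMI count, and with more variable genes the share of regulatory T cells among CD4 lineage cells was higher in the anti-CTLA-4 library, 41.8% against 33.8%. The conventional CD4 T cell share of T cells was then 24.7% against 27.1%, a turned direction. At a finer clustering the CD8 T cell share of T cells was 18.2% against 26.6%. Cd40lg, one of the genes that name the conventional CD4 class, also differed between the libraries within that class, and whether the size of the class depends on that gene was not tested. The CD3+ sort and the lower depth of the IgG library bear on every share. Haemoglobin RNA was also higher in the anti-CTLA-4 library, at a median log2 ratio of 5.35 over all T cells. Whether carry-over of blood bears on the shares was not tested. Cluster names rested on markers fixed beforehand, but the rule that applied them was set after seeing the data, and it left 6 clusters unnamed. The largest was low in UMIs, rich in long transcripts such as Ahnak and Macf1, and held 8.07% against 20.3% of T cells. One led by the naive T cell genes Lef1, Ccr7 and Igfbp4 held 16.3% against 12.3%. Cd8a was read in 49.2% and Cd4 in 7.04% of its cells, so the CD8 T cell-like share may leave out naive CD8 T cells. One led by the interferon-induced genes Ifit3, Rsad2 and Isg15 held 5.06% against 2.70%. A small one led by the myeloid gene Chil3 with histone and other myeloid transcripts held 0.415% against 1.34%. A further unnamed cluster joined T cell transcripts to the microglial and macrophage transcripts C1qa, C1qb and Apoe and held 11.8% against 5.05% of all filtered cells. The last, led by the choroid plexus gene Ttr, held 0.644% against 0.585%. Low-UMI clusters together held 8.93% against 23.4% of filtered cells. All of them count as T cell clusters, so they lower the shares of T cells held by other clusters more in the IgG library. This holds for the unnamed and NK-like clusters as well.

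**Figure D1:**
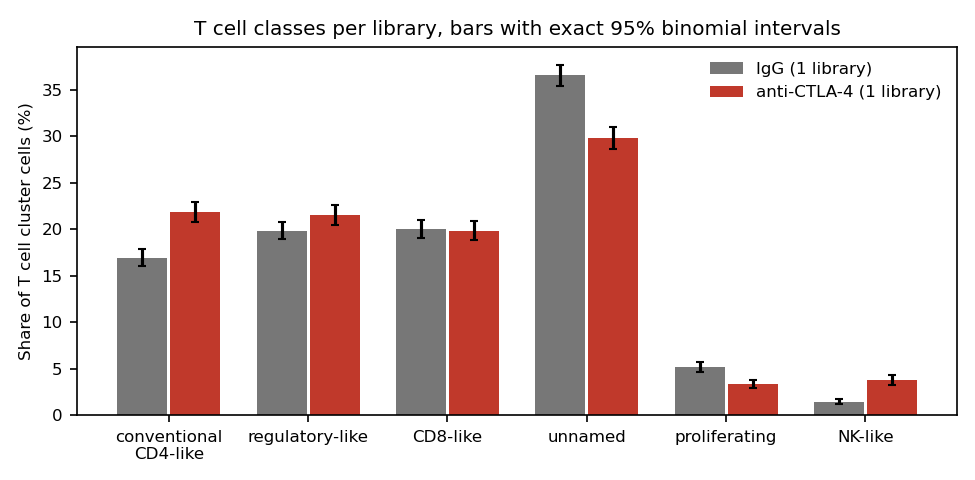
Share of the T cell cluster cells in each class (y axis, %) for the IgG library (grey bars, 7032 cells) and the anti-CTLA-4 library (red bars, 5789 cells), with exact binomial intervals that cover counting error only. The conventional CD4-like bars stand at 16.9% and 21.8%, and the CD8-like bars at 19.99% and 19.8%.

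In conventional CD4 T cell-like cells the anti-CTLA-4 library held more RNA for Tnf, Cxcr6 and Csf1 and less for Mt1, Gzma and Gzmb, with a higher median over interferon response genes and a lower one over G2 and M phase genes. For these granzymes free RNA from other cells was not excluded. Tnf (ENSMUSG00000024401), the gene of tumor necrosis factor, stood at 113 against 33.2 CPM, 3.41-fold higher (log2 1.77, 1.44 to 2.12). Cxcr6 (ENSMUSG00000048521), a chemokine receptor of tissue T cells, stood at 501 against 180.4 CPM (log2 1.47, 1.33 to 1.62). Csf1 (ENSMUSG00000014599), the growth factor of macrophages and microglia, stood at 68.3 against 24.4 CPM (log2 1.49, 1.09 to 1.90). Lower values were led by Mt1 (ENSMUSG00000031765), a metallothionein, at 17.4 against 134 CPM (log2 -2.94, -3.35 to -2.55). The class summed 3629153 UMIs from 1264 anti-CTLA-4 cells and 2710231 UMIs from 1191 IgG cells, and its 2 clusters had nearly the same weight in both libraries, with 31.2% and 31.1% of the class in the cluster led by Ccl1, Ccl4 and Ifng and the rest in a cluster that Cd40lg and Cxcr6 helped to define. At a finer clustering the class was uneven, with 43.0% of its anti-CTLA-4 and 16.7% of its IgG cells in a cluster led by Cd40lg and Cxcr6, 21.1% and 28.7% in one led by Lgals7 and Igfbp7, and 25.2% and 38.6% in an unnamed one led by Ramp3 and Rflnb, so ratios within the class may reflect this mix. With classes set from UMIs per cell, drawn from all T cell clusters including unnamed and proliferating ones, Cxcr6 stood at 1.43 and Tnf at 1.57.

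The other genes of highest ratio were Xcl1, a chemokine for cross-presenting dendritic cells (1.41), the AP-1 factors Jun (1.39) and Fos (1.19), Ckb, a creatine kinase (1.32), Lta, lymphotoxin alpha (1.31), Ccl1, a ligand of Ccr8 (1.24), and Ech1, an enzyme of fatty acid oxidation (1.18). Jun, Fos, Xcl1 and Ech1 were also higher in B and dendritic cells, at 0.91, 1.15, 0.81 and 1.02, and Cxcr6 stood at 0.50 there. When classes were set from UMIs per cell in place of clusters, Ccl1 stood at 0.35, Jun at 0.72 and Xcl1 at 3.00. Ccl1 was higher in sum but not in its share of cells: at 1000 UMIs per cell it was read in 5.15% (3.99 to 6.53) of 1242 anti-CTLA-4 and 7.67% (6.18 to 9.37) of 1135 IgG cells of the class, with 22 and 56 shallower cells left out, against 0.332% and 1.81% of B and dendritic cells, and before thinning in 7.04% and 10.6% at median depths of 2426 and 1964 UMIs. The genes of lowest ratio were the replication histones Hist1h2ab (-2.44), Hist1h3f (-2.38), Hist1h3e (-1.70), Hist1h1b (-1.70), Hist1h4d (-1.65) and Hist1h2ae (-1.61), with Sv2c, a synaptic vesicle protein (-2.19), Fkbp5, a glucocorticoid-induced co-chaperone (-1.64), and Gzma, granzyme A (-1.80). Histone genes have near-identical copies, so single histone values are uncertain, and Hist1h2ae stood at -0.88 with classes from UMIs per cell. In B and dendritic cells of the same libraries Mt1 stood at -1.69, Fkbp5 at -1.76 and Gzma at -1.24. Cd3e was also read in 36.5% of anti-CTLA-4 and 40.4% of IgG B and dendritic cells before thinning. T cell RNA in those barcodes may add to their values, above all for Gzma, Xcl1 and Cxcr6, and this was not tested.

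Il2, Il21 and Cd40lg were higher in the anti-CTLA-4 library. Il2, the T cell growth factor, stood at 1.96, 1.37 to 2.60, Il21, a B cell and CD8 T cell helper cytokine, at 1.34, 0.79 to 1.92, and Cd40lg, the ligand through which helper T cells act on antigen-presenting cells and itself a marker that named the class, at 0.99, 0.78 to 1.21. Ifng, interferon gamma, stood at 224 against 153 CPM (log2 0.55, 0.38 to 0.72), but at -0.02 with classes from UMIs per cell and 1.17 without cells holding myeloid UMIs, and the first of these settings moved the median of all genes by -0.10, so the size of its ratio depended on how the class was set. Csf2, the gene of GM-CSF, stood at -0.47, -1.26 to 0.32 on few UMIs. Tbx21, the master factor of Th1 cells, stood at 0.67, 0.29 to 1.07, and Cxcr3, a Th1 chemokine receptor, at 0.83, 0.63 to 1.04. The inhibitory receptors Pdcd1 and Lag3 stood at 0.55 and 0.55, while Havcr2 stood at -0.99 and Ctla4, the target of the antibody, at -0.67, -0.86 to -0.47. Ctla4 was lower in sum, but its share of cells was close in both libraries. After thinning it was read in 11.4% (9.64 to 13.2) of anti-CTLA-4 and 11.5% (9.74 to 13.5) of IgG cells of the class. Before thinning the shares were 24.7% and 24.1%, at median depths of 2426 and 1964 UMIs. Gzmb stood at -1.45 and Prf1, perforin, at -1.42. The cytotoxicity list, which holds both, stood at -0.35 in B and dendritic cells, with 5 of 13 members lower and 1 higher. Whether free RNA gave the Gzmb and Prf1 values was not tested. The regulatory cytokine Il10 stood at -1.48, -2.55 to -0.47 on few UMIs, and Ccr8 and Itga1 at 0.98 and 0.86. With classes from UMIs per cell Il21 stood at 0.60 and Itga1 at 0.24, and without cells holding myeloid UMIs Il10 stood at -3.18. Icos (-0.01), Tigit (0.00), Tnfrsf18 (-0.02) and Ccl4 (0.05) were nearly equal in both libraries.

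Of the lists of related genes, a member counted as higher or lower when its CPM differed at least 1.5-fold. The interferon response had a median of 0.34, 0.26 to 0.49, at percentile 99.99 of 10000 random lists matched on expression. In it 8 of 27 members were higher, such as Irf7 (0.84) and Rtp4 (0.84), and 0 lower, while 19 were neither, such as Irgm1 (-0.45). Myeloid and microglial transcripts, which T cells should lack, were higher in the same class, with a median of 0.55, 0.42 to 0.73 and 9 of 18 members higher, C1qa at 1.29 among them. Without cells that held a C1qa, C1qb, C1qc, Apoe or Lyz2 UMI the interferon median was 0.21. The interferon list stood at 0.05 in B and dendritic cells and at 0.31 in microglia, monocytes and macrophages. The Th1 list had a median of 0.07, -0.02 to 0.18 and a mean of 0.30, with Il2 and Tnf among 5 higher members, 1 lower, Il18rap at -0.97, and 12 neither. Tissue residency stood at 0.30, 0.04 to 0.43, with 4 of 13 higher, Cxcr6 and Xcl1 first, and 1 lower, Prdm1 at -0.69. The chemokines made by T cells stood at 0.43, 0.08 to 0.68 with 3 of 6 higher, led by Xcl1 and Ccl1, the latter not in its share of cells. The naive and memory precursor list stood at -0.36, -0.45 to -0.24, with 3 of 14 lower, Dapl1 (-0.75) among them, and 2 higher, Id3 at 0.66. With classes from UMIs per cell that median was -0.15. Inhibitory receptors and exhaustion genes stood at 0.17, -0.02 to 0.32, with 1 member higher and 3 lower. Immediate early genes, which tissue dissociation also induces, stood at 0.45, 0.36 to 0.58, with 6 of 16 higher, Jun and Fos among them.

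The G2 and M phase list was lower in the anti-CTLA-4 library, while few S phase genes were. The G2 and M phase list had a median of -1.10, -1.35 to -0.73, below all 10000 random lists, with 12 of 15 members lower and none higher in this class. Mki67, a proliferation marker, stood at -0.73 (-1.48 with classes from UMIs per cell), Top2a at -0.95 and Ube2c at -1.19. The S phase list stood at -0.28, -0.49 to -0.17, with 4 of 16 lower. The G2 and M phase list was also lower in B and dendritic cells, at -1.01, and in microglia, monocytes and macrophages, at -0.61, but higher in proliferating cells, at 0.36 (0.12 to 0.42). Proliferating cells lay in one cluster with 156 anti-CTLA-4 and 206 IgG cells and in another with 36 and 158. The value of 0.36 may reflect this mix. The cytotoxicity list had a median of -0.10, -0.27 to 0.06 and a mean of -0.95, pulled down by a small number of granzyme genes, with 6 of 15 members lower and 2 higher, Ctsw at 0.76 and Klrd1 at 0.75.

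**Figure D2:**
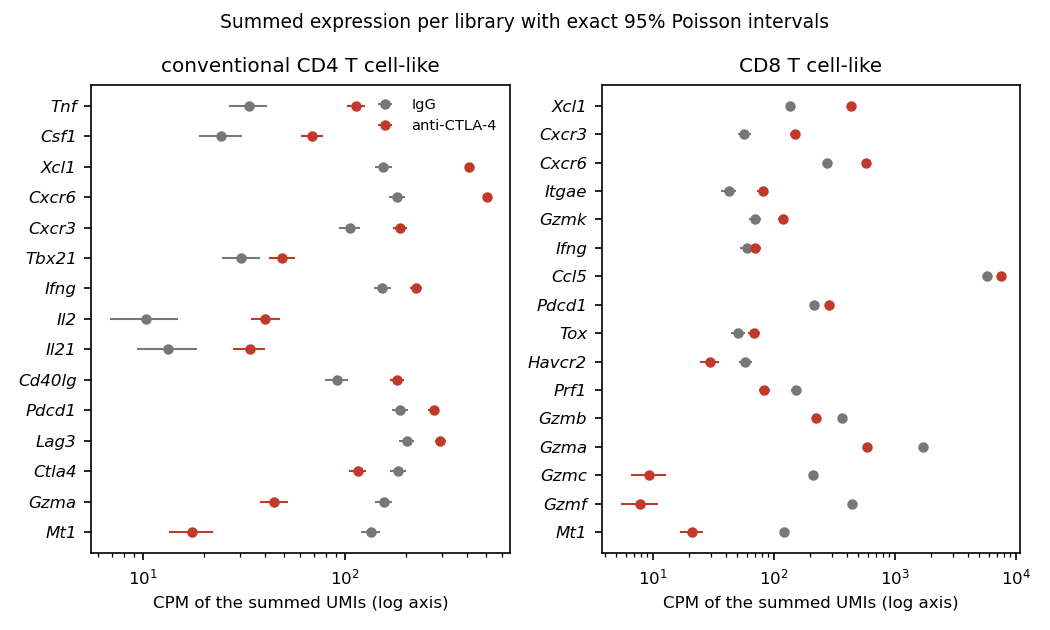
CPM of the UMIs summed over a class (x axis, log scale) for named genes in conventional CD4 T cell-like cells (left) and CD8 T cell-like cells (right), IgG library in grey and anti-CTLA-4 library in red, 1 library each, with exact Poisson intervals that cover counting error only. Tnf lies at 33.2 and 113 CPM in the CD4 panel, and Gzmf at 445 and 7.91 CPM in the CD8 panel.

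In regulatory T cell-like cells the list of lineage genes had a median near 0 over members that differed both ways, while the anti-CTLA-4 library had a higher median over interferon response genes and a lower one over G2 and M phase genes. The lineage list holds all the markers that named the class, Foxp3, Il2ra, Ikzf2, Tnfrsf4 and Capg among them. Its median near 0 may therefore be partly built in. Foxp3, the lineage factor, stood at 498 against 456 CPM (log2 0.13, 0.02 to 0.24), and Ctla4 at 389 against 469 CPM (log2 -0.27, -0.39 to -0.16). Tnfrsf4, the costimulatory receptor OX40, was among the members at higher level, at 1446 against 942 CPM (log2 0.62, 0.55 to 0.69). Mki67 was lower, at 53.0 against 140.0 CPM (log2 -1.40, -1.67 to -1.14; -0.59 with classes from UMIs per cell). The class summed 3153132 UMIs from 1244 anti-CTLA-4 cells and 2664545 UMIs from 1396 IgG cells. The low-UMI cluster led by Itgb8 and Ikzf2 held 15.1% of its anti-CTLA-4 cells and 28.6% of its IgG cells. Ikzf2, Helios, stood at -0.08, and at 0.05 without that cluster. At a finer clustering 78.4% of the anti-CTLA-4 and 37.2% of the IgG cells of the class lay in a cluster led by Foxp3, and 1.77% and 31.0% in one led by Tff1, which may mark the IgG library in place of a cell type.

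The genes of highest ratio in this class were Coro1b, a coronin of the actin skeleton (1.31, 1.09 to 1.55), Ube2l6, a conjugating enzyme for the interferon-induced modifier ISG15 (1.22), Pnp, a purine phosphorylase (1.11), Tuba1a, an alpha-tubulin (1.1), Eif4e3, a cap-binding factor (1.09), and Zfp36, which destabilises cytokine transcripts (1.09). Those of lowest ratio were Klf9, a glucocorticoid-induced factor (-2.27, -2.76 to -1.80), and the histones Hist1h2ab (-2.23), Hist1h3f (-2.07), Hist2h2ac (-1.88), Hist1h4d (-1.88) and Hist1h1b (-1.86). With classes from UMIs per cell Hist1h2ab stood at -1.38, Hist2h2ac at -0.60 and Hist1h1b at -0.53. Coro1b was also higher in B and dendritic cells, at 0.67, and Klf9 lower there, at -2.62. In the regulatory T cell program 4 of 21 members were higher, such as Capg (1.04), Klrg1 (0.66) and Ccr8 (0.65), 1 was lower, the ST2 receptor gene Il1rl1 (-1.19), and 16 were neither. The median of that list was 0.06, -0.05 to 0.19, and -0.12 with classes from UMIs per cell. Il2ra (-0.03), Tnfrsf9 (0.13), Icos (0.11) and Il10 (-0.16) were close in both libraries. Tnfrsf18 stood at 0.33, Lag3 at 0.47, Cxcr3 at 0.60, Cxcr6 at 0.92 and Itgae at -0.34. Il1rl1 and Itgae were among the leading genes of the low-UMI cluster with 15.1% of anti-CTLA-4 and 28.6% of IgG cells of the class. Their lower values may reflect that mix. Tnf stood at 1.45, and at 0.62 without cells holding myeloid UMIs. Gzma stood at -1.81 (-3.56 without the highest doublet scores) and Gzmb at 0.03.

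The interferon list in regulatory T cell-like cells had a median of 0.49, 0.38 to 0.55, above all 10000 random lists, with 8 of 27 members higher, Socs1 (1.05) and Irf7 (0.75) among them, and 0 lower. The myeloid and microglial list stood at 0.29, 0.20 to 0.47 beside it. The G2 and M phase list stood at -0.92, -1.32 to -0.56, with 11 of 17 lower and 1 higher, and S phase at -0.21, -0.36 to -0.04. Immediate early genes stood at 0.42, 0.28 to 0.58, with Zfp36 and Fos (1.03) highest. Tissue residency stood at -0.32, -0.42 to -0.12, with Prdm1 (-0.83) and Rgs2 (-0.60) lower and Cxcr6 higher, and the naive and memory precursor list at -0.19, -0.37 to -0.02 with a mean of 0.03. The Th1 list stood at -0.10, -0.20 to 0.04, cytotoxicity at -0.25, -0.36 to -0.01 with a mean of -0.77, inhibitory receptors at -0.10, -0.25 to 0.12, and T cell chemokines at -0.04, -0.17 to 0.10.

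**Figure D3:**
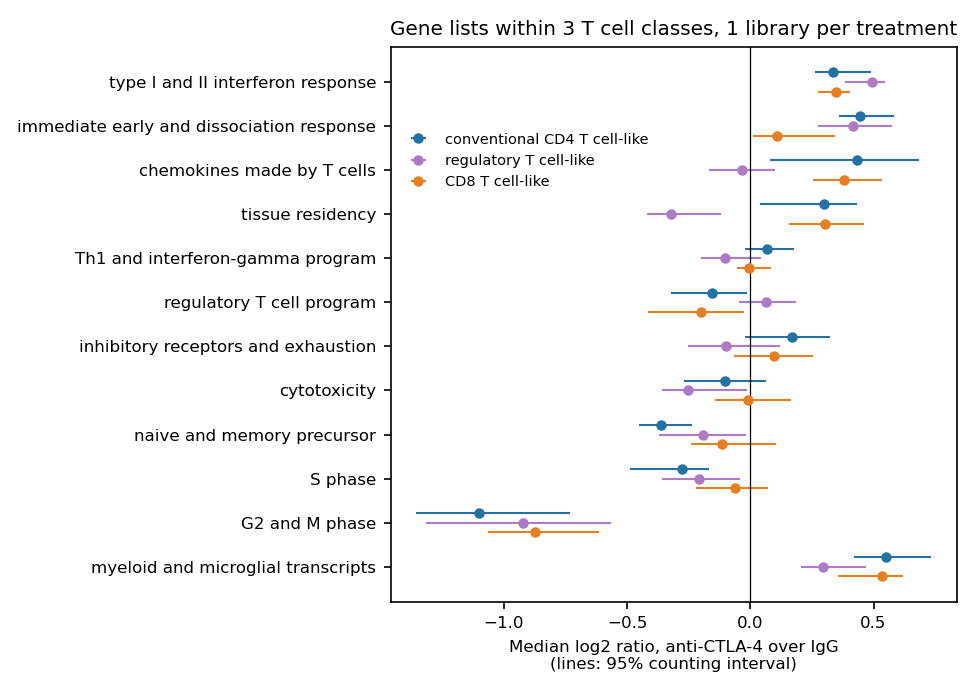
Median log2 ratio of CPM, anti-CTLA-4 over IgG (x axis), of 12 gene lists in conventional CD4 (blue), regulatory (purple) and CD8 T cell-like cells (orange), with lines for the interval from Poisson draws of the counts, 1 library per treatment. Interferon response genes lie between 0.34 and 0.49, and G2 and M phase genes between -1.10 and -0.87.

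In CD8 T cell-like cells the anti-CTLA-4 library held less RNA for several granzymes and more for Xcl1, Cxcr3 and Cxcr6. Gzmf (ENSMUSG00000015441), granzyme F, was 56.3-fold lower, at 7.91 against 445 CPM (log2 -5.81, -6.36 to -5.32), and Gzmc (ENSMUSG00000079186), granzyme C, was 22.6-fold lower, at 9.35 against 211 CPM (log2 -4.50, -5.0 to -4.04). Gzma (ENSMUSG00000023132) stood at 594 against 1714 CPM (log2 -1.53, -1.59 to -1.46), Gzmb, granzyme B, at -0.70, -0.82 to -0.58 and Prf1 at -0.86, -1.05 to -0.67. Higher values were led by Xcl1 at 436 against 137 CPM (log2 1.67, 1.54 to 1.81), Cxcr3 at 148 against 57.1 CPM (log2 1.38, 1.16 to 1.6) and Cxcr6 at 574 against 276 CPM (log2 1.05, 0.95 to 1.15). The class summed 4172858 UMIs from 1147 anti-CTLA-4 cells and 4307729 UMIs from 1406 IgG cells. The cluster led by Gzmf, Gzma and Klrd1 held 67.0% of the anti-CTLA-4 and 65.5% of the IgG cells of the class, and the other cluster was led by Gzmk and Ccl5. A finer clustering also gave the CD8 name to a cluster led by Sema6d and Styk1, with 91 anti-CTLA-4 and 496 IgG cells, nearly all of which lay in the unnamed low-UMI cluster here.

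Gzmc and Gzmf are neighbouring members of a family of close copies, so the split of reads between them is uncertain. Thinned to 1000 UMIs per cell, 0.175% (0.0211 to 0.629) of 1146 anti-CTLA-4 and 10.3% (8.75 to 12.0) of 1378 IgG CD8 T cell-like cells held a Gzmf UMI, with 1 and 28 shallower cells left out. In B and dendritic cells, which should lack the gene, the thinned shares were 0 of 301 cells, which allows a share of up to 0.997%, and 3.02% (1.46 to 5.49) of 331 IgG cells, at median depths of 4288 and 3632 UMIs against 3142 and 2691 in the CD8 class. Before thinning, the shares in B and dendritic cells were 0 of 304 cells, which allows up to 0.987%, and 5.85% (3.61 to 8.89) of 342 IgG cells, against 0.697% (0.302 to 1.37) and 15.8% (13.9 to 17.8) in the CD8 class. With and without thinning, the IgG share in the CD8 class stood above that of B and dendritic cells, and the anti-CTLA-4 share lay under the limit that 0 cells allow. With classes from UMIs per cell Gzmf stood at -5.46 and Gzmc at -4.49. As a mean over cells the ratios were -4.85 and -3.53, and without cells holding myeloid UMIs -7.10 and -3.51. In IgG cells of the class with 2 or more Gzmc or Gzmf UMIs, no receptor beta gene took more than 24.1% of the receptor beta UMIs.

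The other genes of highest ratio were Rtp4, an interferon-induced chaperone (1.06), Rgs10, a regulator of G protein signals (1.01), Pim2, a survival kinase (1.0), Jun (0.99), Ech1 (0.96), Car2, a carbonic anhydrase (0.95), and Coro1b (0.94). Those of lowest ratio also held Mt1 (-2.53, -2.88 to -2.21), Tff1, a trefoil factor (-2.15), Fkbp5 (-1.63) and the histones Hist1h3f (-2.51), Hist1h2ab (-2.23), Hist1h1b (-1.69) and Hist1h4d (-1.47). With classes from UMIs per cell Mt1 stood at -1.83, Hist1h2ab at -1.59 and Hist1h1b at -1.11. Xcl1, Cxcr6 and Rtp4 were also higher in microglia, monocytes and macrophages, at 1.6, 1.25 and 1.02. Before thinning Cd3e was read in 63.2% of anti-CTLA-4 and 60.3% of IgG microglia-like cells, and in 72.3% and 57.1% of monocyte or macrophage-like cells. T cell RNA in those barcodes may therefore add to the Xcl1 and Cxcr6 values. Itgae, the CD103 integrin of tissue-resident cells, stood at 0.93, and at 0.34 with classes from UMIs per cell. Gzmk, a marker that named the class, stood at 0.75, and at 0.25 in that setting. Ccl5 stood at 0.37, Ccl4 at 0.51, Cd69 at 0.65, Tbx21 at 0.47 and Ifng at 0.22, -0.02 to 0.47. Among inhibitory receptors Havcr2, the TIM-3 gene, was lower (-0.98, and -1.77 with classes from UMIs per cell), while Pdcd1, Lag3 and Tigit stood at 0.41, 0.17 and 0.27 and lay on the other side of 0 in that setting, at -0.05, -0.13 and -0.06, where the median of all genes moved by -0.16. Tox, a factor of exhausted cells, stood at 0.45, Tnfrsf9 at -0.62 and Il2ra at -0.79. Ccr7 stood at -0.80 and Il7r at 0.26, and at 0.13 and -0.16 with classes from UMIs per cell, so Il7r lay at the shift of all genes and Ccr7 past it on the other side of 0.

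The cytotoxicity list in CD8 T cell-like cells had a median of -0.01, -0.14 to 0.17 but a mean of -0.66. Of its 16 members 5 were lower, the granzymes Gzma, Gzmb, Gzmc and Gzmf with Prf1, 3 were higher, Fasl (0.91) and Gzmk among them, and 8 were neither. Tissue residency stood at 0.30, 0.16 to 0.46, with 5 of 13 higher, such as Xcl1, Cxcr6 and Itgae, and 1 lower, Prdm1 (-0.79). T cell chemokines stood at 0.38, 0.26 to 0.53, with 1 of 6 higher and 1 lower, and chemokine receptors at 0.05, -0.37 to 0.25, with 3 of 11 higher and 4 lower. Inhibitory receptors and exhaustion genes stood at 0.09, -0.06 to 0.25, with 3 higher, Cd101 (0.82) and Cd160 (0.70) among them, and 2 lower, Havcr2 and Nr4a3 (-1.19). That median was -0.25 with classes from UMIs per cell. The interferon list stood at 0.35, 0.27 to 0.40, with 5 of 27 higher, such as Rtp4 and Irf7 (0.75), and 1 lower. Myeloid and microglial transcripts stood at 0.53, 0.35 to 0.62, with 9 of 19 higher. The G2 and M phase list stood at -0.87, -1.06 to -0.62, with 11 of 16 lower, Birc5 (-1.12) and Mki67 (-0.95, and -1.56 with classes from UMIs per cell) among them, and S phase at -0.06, -0.22 to 0.07. The naive and memory precursor list stood at -0.12, -0.24 to 0.11 with a mean of 0.05, with Id3 at 1.22 and Ccr7 lower, and turned to 0.11 with classes from UMIs per cell. The Th1 list stood at 0.00, -0.06 to 0.09 and immediate early genes at 0.11, 0.01 to 0.34.

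The TCR libraries gave the sizes of T cell clones under each treatment. The IgG library held 2271 clonotypes in 3279 cells and the anti-CTLA-4 library 3429 clonotypes in 5514 cells. Clonotypes of at least 2 cells held 46.9% (45.6 to 48.2) of anti-CTLA-4 and 39.1% (37.5 to 40.8) of IgG cells, a difference of 7.77 points (5.64 to 9.89). Clonotypes of at least 10 cells numbered 46 and 18 and held 20.7% (19.7 to 21.8) and 14.6% (13.4 to 15.8) of cells. The largest clonotype ran the other way, with 182 cells, 5.55% (4.79 to 6.39), in the IgG library and 146 cells, 2.65% (2.24 to 3.11), in the anti-CTLA-4 library. Their TRB junctions read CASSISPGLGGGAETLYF and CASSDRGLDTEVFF.

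The 10 largest clonotypes together held 10.8% (10.0 to 11.7) and 11.6% (10.6 to 12.8), a difference of -0.805 points (-2.20 to 0.548) that was not detectable at this depth. Drawn down to the 3279 cells of the IgG library, the anti-CTLA-4 library held 42.2% of cells in expanded clonotypes (41.0 to 43.6 over 1000 draws), so the gap narrowed to 3.11 points. Clonotypes of at least 10 cells then numbered 23.0 on average against 18 and held 16.0% against 14.6% of cells, a gap of 1.44 points in place of 6.17. Receptor capture differed as well. The TCR libraries held 5514 anti-CTLA-4 and 3279 IgG cells, beside 5789 and 7032 cells in the T cell clusters of the RNA libraries. Drawing down evens the number of cells but not which cells gave a receptor. Both chains were read in 82.8% of anti-CTLA-4 and 64.7% of IgG cells, and only a TRB chain in 13.6% and 29.2%. Over clonotypes with both chains the gap in the share of TCR cells in expanded clonotypes was 2.83 points, and merging clonotypes by TRB junction gave 1.51 points. The share of TCR cells in the 10 largest clonotypes was 13.1% against 17.9% over clonotypes with both chains. Shannon evenness of clonotypes was 0.927 and 0.936, and its order turned over clonotypes with both chains, 0.915 and 0.909, and at equal cell number, 0.940 and 0.936. The Gini coefficient of clonotype sizes was 0.357 and 0.292, and 0.312 for the anti-CTLA-4 library at equal cell number. Only 7 clonotypes had identical nucleotide junctions in both libraries, with 50 anti-CTLA-4 and 16 IgG cells, while 96 TRB junctions were shared as amino acid sequences, out of 3120 and 1861. Cells of one clone are not independent, so these intervals are too narrow for clone numbers. The clonotype lists carry no cell barcodes, so no clone was assigned to a T cell class.

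**Figure D4:**
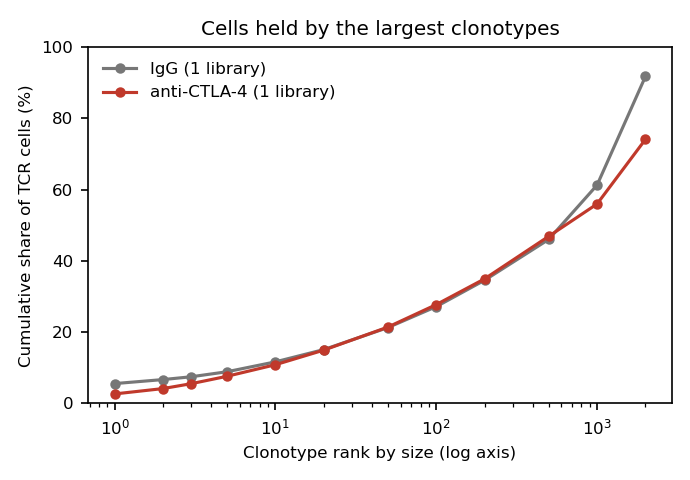
Cumulative share of cells with a TCR (y axis, %) held by clonotypes ranked by size (x axis, log scale), IgG in grey and anti-CTLA-4 in red, 1 library each, with points at 12 ranks. The curves start at 5.55% and 2.65% for the largest clonotype and lie at 11.6% and 10.8% for the 10 largest.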

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

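The tests of low-UMI barcodes, of droplets with 2 cells and of free microglial RNA, and the counts of invariant junctions, were chosen only after the result was seen. Klrg1, an inhibitory receptor gene of effector and regulatory cells, differed between T cell classes in the direction of its ratio, at 0.66, 0.36 to 0.95 in regulatory and -1.21, -2.43 to -0.06 in conventional CD4 T cell-like cells, where its UMIs were few. The gap of 1.87 between those log2 ratios was not tested. In the receptor sequences, which the class comparisons do not use, 0.472% (0.308 to 0.690) of anti-CTLA-4 cells in 25 clonotypes carried the invariant alpha junction of NKT cells, against 0.0915% (0.0189 to 0.267), or 3 cells, in the IgG library. The junction of mucosal-associated invariant T cells was read in 2 anti-CTLA-4 cells and 0 IgG cells. Only a TRB chain was read in 13.6% of anti-CTLA-4 and 29.2% of IgG cells, where an alpha junction cannot be seen. A signal outside the T cell classes came from the cluster that joined T cell and microglial transcripts, with 11.8% of filtered anti-CTLA-4 cells and 5.05% of IgG cells.

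Gzmf and Gzmc were far lower in anti-CTLA-4 CD8 T cell-like cells, and Gzma was also lower in conventional CD4 T cell-like cells. Against a single expanded clone as the IgG source stands that Trbv19, the most used beta gene among 146 IgG CD8 T cell-like cells with 2 or more Gzmc or Gzmf UMIs, took 24.1% of their Trbv UMIs, under the bound of 30% set beforehand, though above 13.6% in IgG cells without those UMIs. In anti-CTLA-4 cells of the class without those UMIs Trbv19 took 2.53%. Trbv3 and Trbv1 took 16.2% and 15.4% in the 146 IgG cells. A small number of clones, in a pool of 3 tumors, was therefore not excluded. For Gzma in conventional CD4 T cell-like cells, free granzyme RNA and expression cannot be told apart: at 1000 UMIs 3.93% of IgG B and dendritic cells held a Gzma UMI against 9.69% of conventional CD4 T cell-like cells, with 11 and 56 shallower cells left out and median depths of 3632 and 1964 UMIs, but without thinning the intervals overlapped, 14.6% (11.05 to 18.8) and 18.9% (16.7 to 21.2). The bound set beforehand was met, yet it was wrong, because free RNA per droplet does not grow with the depth of the cell. An effect of the antibody on cytotoxic cells may explain the CD8 values, but treatment cannot be separated from the library or the pooled mice, and this was not tested.

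G2 and M phase genes were lower in each of the 3 anti-CTLA-4 T cell classes, with list medians below -0.8, but over all T cells the median was -0.37, with 7 of 19 members lower and 12 neither, at percentile 5.65 of the random lists, 95% of which lay between -0.42 and 0.12. Clusters under the UMI limit are argued against as the source over all T cells, since the median was -0.46 without them. The conventional CD4 and CD8 classes hold no such cluster. Barcodes of poor quality above that limit are not covered by this test. Free RNA of dividing cells is a candidate source that met its bound, with the list at -1.01 (-1.45 to -0.61) in B and dendritic cells. The list stood at -1.15 in T cells outside the proliferating class and the low-UMI clusters. It stood at 0.36 within the proliferating class, whose clusters differ in weight between the libraries. The test cannot decide on this source. Only 8 of 19 members were measured in B and dendritic cells, and Cd3e was read in 36.5% of anti-CTLA-4 and 40.4% of IgG ones before thinning. B cells were 95 of 304 anti-CTLA-4 and 58 of 342 IgG cells of that group, so a change of mix may also give the value. Without the low-UMI clusters and the proliferating cluster rich in mitochondrial RNA, which held 0.622% against 2.25% of T cells, the median was -0.13. The value over all T cells thus depends on that cluster. A lower rate of division after anti-CTLA-4 stays open as an untested explanation.

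Barcodes with T cell and microglial RNA were more frequent after anti-CTLA-4, and at 1000 UMIs per cell C1qa was read in 78.4% of these anti-CTLA-4 barcodes and 76.4% of the IgG ones, Cd3e in 58.9% and 45.5%, with 29 and 32 shallower barcodes left out, while 8.21% and 3.70% of conventional CD4 T cell-like cells held C1qa and 33.8% and 30.2% of microglia-like cells held Cd3e. Before thinning, at median depths of 3330 and 2620.5 UMIs, the shares were 95.1% and 91.1% for C1qa and 86.7% and 74.9% for Cd3e, against 63.2% and 60.3% for Cd3e in microglia-like cells at median depths of 4719 and 3184, of which 16 and 10 had been left out. Droplets loaded with 2 cells at random are argued against, since there were 34.2 times as many such anti-CTLA-4 barcodes as random pairs at a doublet rate of 7% would give, and 29.7 times in the IgG library. Free microglial RNA spread evenly over all droplets is argued against, since without thinning 12.3% of anti-CTLA-4 and 4.67% of IgG barcodes of the T cell clusters and this cluster held 3 or more C1qa UMIs, 35.0 and 61.3 times what a Poisson draw gives at the level bounded by the B and dendritic cells with any C1qa UMI (20.7% and 12.0%), though 6.91% and 3.51% of those cells also held 3 or more, so RNA unevenly spread over droplets stays open, and a first test at 1000 UMIs, against a Poisson draw with the barcodes' own mean, gave 4.94 (4.46 at the lower end) and 21.6 times and did not reach its bound of 5 in both libraries. T cells held to microglia or carrying their fragments may also explain the barcodes, and microglia themselves were 3.25% against 1.41% of filtered cells, but no biological explanation was tested.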

How the results depend on the processing

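No paired analysis was possible because each treatment had 1 pooled library. The alternatives without low-UMI clusters, without the highest Scrublet scores and without cells holding myeloid UMIs were chosen only after the data were seen. Of 126 alternative values for shares, lists and clonotype measures, 87 stayed within the interval of the reported value, 30 moved beyond it and 9 crossed 0 from a reported value whose interval (for evenness, the spread of draws at equal cell number) excluded 0, and of 1714 values for 168 gene and class pairs 1565, 137 and 12 did so. Keeping Scrublet doublets changed nothing since 0 were marked, which covers 168 of the gene values. A changed UMI minimum cannot move the ratio of a single gene. The 168 gene values at the lower minimum and the 156 at 100 UMIs were therefore also bound to stay the same. The difference in regulatory T cells among CD4 lineage cells, -4.36 points, was 0.390 at coarser and -8.85 at finer resolution, 8.02 with more variable genes, -9.91 with centred values, -12.9 and 0.989 with a looser and a stricter cell filter, 2.85 with classes from UMIs per cell, 0.0158 with those after thinning, and -0.0495 without low-UMI clusters. The conventional CD4 T cell share of T cells, 4.90 points higher, was -2.39, 2.70, 2.65 and 1.43 with more variable genes, classes from UMIs per cell, the same thinned, and without low-UMI clusters. The CD8 T cell share of T cells, -0.181 points, was -8.41 at finer resolution, -5.0 with more variable genes, -2.70 centred, 2.11 and -8.04 under the looser and stricter filter, -3.17 and -6.46 with classes from UMIs per cell and thinned, and -5.06 without low-UMI clusters. With classes from UMIs per cell, list medians were -0.12 for the regulatory T cell program in regulatory T cells, -0.25 for inhibitory receptors and exhaustion in CD8 T cells, 0.48 for the interferon response in CD8 T cells, -0.15 for the naive and memory precursor list in conventional CD4 T cells and 0.11 for the naive and memory precursor list in CD8 T cells. The last was -0.27 as a mean over cells and -0.31 without cells holding myeloid UMIs, where the interferon response in conventional CD4 T cells was 0.21. The share of TCR cells in expanded clonotypes, 7.77 points higher, was 2.83 over clonotypes with both chains, 2.16 with exactly 1 of each, 1.51 merged by TRB junction and 3.11 at equal cell number. The share of TCR cells in the 10 largest clonotypes, -0.805 points, was -4.76 and -4.43 in the first and second of these. Shannon evenness of clonotypes, a difference of -0.00878, was 0.00614, 0.00704, -0.00384 and 0.00396 in the same order. Genes that crossed 0 in this sense with classes from UMIs per cell were Ifng (-0.0158) and Ccl5 (0.0544) in conventional CD4, Foxp3 (-0.17) and Ifng (0.78) in regulatory, and Pdcd1 (-0.0501), Lag3 (-0.13), Tigit (-0.0559), Il7r (-0.16) and Ccr7 (0.13) in CD8 T cell-like cells. These classes use Foxp3 UMIs, so the Foxp3 value says nothing about its direction. In regulatory T cell-like cells Ccl5 stood at -0.14 without the highest Scrublet scores, and Ikzf2 at 0.0103 with median-of-ratios factors, which moved all genes of the class by 0.0900, and 0.0510 without low-UMI clusters. Classes from UMIs per cell moved the median of all genes by -0.10 in conventional CD4 and -0.16 in CD8 T cell-like cells, which is further than Ifng in the first and Pdcd1, Lag3 and Tigit in the second lay past 0 and close to where Il7r lay, and the other scalings by under 0.1. For the others the cause was not tested. Classes from UMIs per cell also hold cells of the unnamed, proliferating and NK-like clusters, so their values compare another set of cells. Lower depth in the IgG library limits shares of cells, and few UMIs limit Il10, Il2 and Klrg1.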

Other observations

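The comparison of cells other than T cells, the replication histones and the glucocorticoid-type genes were chosen only after values had been seen. The CD3+ sort also let through brain and blood cells. Microglia-like cells with P2ry12 and Tmem119 were 3.25% against 1.41% of filtered cells, anti-CTLA-4 against IgG, and monocyte or macrophage-like cells 3.42% against 2.05%. B cell-like cells were 1.25% against 0.707%, dendritic cell-like cells 2.75% against 3.46%, neutrophil-like cells 0.25% against 0.792% and plasma cell-like cells 0.329% against 0.134%. In microglia, monocytes and macrophages the myeloid and microglial list stood at 0.70, with 11 of 20 members higher, and the interferon list at 0.31. In B and dendritic cells those lists stood at 0.09 and 0.05.

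Among lists of other T cell functions, given for conventional CD4, regulatory and CD8 T cell-like cells in turn, chemokine receptors stood at 0.17, -0.04 and 0.05, with Cxcr4, the receptor of stromal CXCL12, at -1.06 in regulatory cells and Cxcr3 high in CD8 cells. The follicular helper list stood at 0.13, 0.16 and 0.23, and in regulatory cells its mean was -0.31, with Izumo1r at 0.49 and Cxcr4 lower. In conventional CD4 cells 3 of 12 follicular members were higher, Il21 among them, and 2 lower, Tox2 at -0.99. The Th17 list stood at 0.27, 0.47 and -0.59, with Tmem176a at 1.05 in regulatory and Maf at -0.59 in CD8 cells. The Th2 list stood at -0.19, -0.65 and -0.76 on few members, with Gata3, the Th2 master factor, at -0.43, -0.57 and -0.51. Costimulation genes stood at -0.01, 0.09 and -0.22, with Cd27 at 0.83 in regulatory cells and Tnfrsf9 at -0.62 in CD8 cells.

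TCR signalling genes stood at 0.26, -0.01 and 0.06, with Cd3g higher at 0.78, 0.62 and 0.62 and the phosphatase gene Ptpn22 at -0.66, -1.04 and -0.50. Apoptosis genes stood at -0.14, -0.40 and -0.17, with the death inducers Bcl2l11 at -1.05, -1.28 and -0.86 and Bbc3 at -1.83 in conventional CD4 cells. Glycolysis stood at 0.04, 0.18 and -0.05, where Pgam1 was higher (0.86 in conventional CD4 cells) and Eno1 lower (-0.81 in CD8 cells). Oxidative phosphorylation stood at 0.01, 0.16 and 0.07, with 0 of 18 members past 1.5-fold in any of the 3 classes. Heat shock genes stood at 0.30, 0.10 and 0.16, with Hspa8 at 0.47, 0.52 and 0.53. The regulatory T cell program stood at -0.16 in conventional CD4 and -0.20 in CD8 cells. Glioma, astrocyte and oligodendrocyte transcripts stood at -0.04, 0.50 and 0.07 on 4 genes, Cnp and Mbp among them. Haemoglobin, measured over all T cells only, stood at 5.35 with 5 of 5 members higher, and Hbb-bs had 1 UMI in the IgG library and 517 in the anti-CTLA-4 library (log2 8.90, 6.42 to 14.21).

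Replication histones had medians of -1.52, -1.82 and -1.40 in the 3 classes, with 23 of 24, 25 of 26 and 22 of 27 members lower, and -1.46 in B and dendritic cells. Glucocorticoid-type genes such as Fkbp5, Klf9, Tsc22d3 and Per1, which corticosteroids induce, had medians of -1.26, -1.05 and -1.03, with 9 of 10, 7 of 9 and 6 of 9 lower. They stood at -0.97 in B and dendritic cells and at -1.71 in microglia, monocytes and macrophages, so the lower values were shared by the cell types measured. Whether this came from the treatment, the mice or the handling of the 2 libraries was not tested.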
